A study of Homo sapiens with 12 samples.

How the data were processed

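The study set out, per its summary, to find genes that ZXDC1 regulates while PMA drives U937 cells toward a monocyte or macrophage phenotype. Per the labels, the cells carried a TRIPZ Tet-On hairpin against ZXDC1 and ZXDC2, doxycycline was given daily at 0.5 µg/mL for 4 days, and 100 nM PMA or 0.1% DMSO came after the first 2 days, for 3 days; the durations are given as the labels state them. RNA was labelled from 100 ng with a 3' IVT kit. The deposited values are on the log2 scale and were made by RMA, per the submitters' processing notes; the version and other steps are not given in the sources used here. They were used without further scaling. The 54675 probe sets had no missing value, and no 2 arrays held identical values.

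Of the probe sets 62 were controls, 41097 paired with 1 gene symbol, 1801 with several, and 11721 with no gene in the table used here. For 41043 of the single-gene probe sets the symbol was brought up to date through the Entrez number, and 54 kept theirs. The probe set with the highest mean over all 12 arrays stood for each gene, which left 19775 genes. No filter on dim genes was used. Probe sets with several genes or none were left out of the gene tests because they cannot be assigned to 1 gene.

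Group means were fitted over all 12 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 8 residual and 5.6 prior degrees of freedom. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 6 comparisons were PMA without and with doxycycline, doxycycline in each agent, doxycycline averaged over both agents, and the interaction. The ZXDC change was also tested by exact permutation of the arrays within agents. Gene lists were tested with camera, at a preset correlation of 0.01 between genes and then with an estimated one, adjusted over the lists of a comparison, and with fry. The 24 lists hold 466 distinct genes, of which 427 were measured and 39 were not measured here. The correlation of the doxycycline effects was tested by the same exact permutation and, after seeing the data, by exchanges within pairs, and the overlap with PMA-changed genes was set beside 100 simulations of unchanged groups. The groups, comparisons, lists, main tests and first set of alternatives were fixed before the data were examined.

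The labels name the arrays of each group as biological replicates 1 to 3. Pairing by these numbers was checked on the data, through the correlation of the arrays' deviations from their group means. Between arrays with and without doxycycline it was 0.57, 0.25 and 0.31 for numbers 1 to 3 in vehicle, and 0.64, 0.29 and 0.32 in PMA. All lie over the limit of 0.1 set beforehand, so the arrays were taken as paired within agents. In vehicle all 6 arrays correlated best with their own number, in PMA 3 of 6 did. The highest correlation between arrays of different numbers was 0.24 in vehicle and 0.39 in PMA. The latter exceeds the 0.29 and 0.32 of PMA numbers 2 and 3. Passing the limit therefore does not settle that PMA arrays numbered 2 and 3 are matched pairs. Across agents the pairs of vehicle and PMA gave 0.16, -0.01 and 0.15, and those of both doxycycline groups 0.20, 0.07 and 0.06, under the limit for at least 1 number. Vehicle with doxycycline against PMA gave 0.23, 0.27 and 0.14, and vehicle against PMA with doxycycline 0.12, 0.10 and 0.12, so 2 of the 4 comparisons across agents lay over the limit too, with 6 of 6 arrays best with their own number in each. The 6-pair fit therefore leaves out a relation across agents that part of the data hold, and the replicate block over all groups includes it. A fit with a replicate block over all groups, numbers 1 to 3, was chosen before the data were seen. A fit with a block for each of the 6 pairs, which has 4 residual degrees of freedom, was added after seeing the data, as were the fit on replicates 2 and 3 alone and the 6-pair fit without each pair. Values called paired in the text come from the 6-pair fit. The number of arrays, 3 per group, limits the precision.

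Named genes followed a rule. ZXDC, its relatives ZXDA and ZXDB, and CCL2, CIITA and BCL6 were always named. Each comparison added the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, or the 5 genes with the smallest p if none was called. Each list added up to 4 called members, at most 2 in each direction, or the member with the smallest p, and ACTB and GAPDH served as reference. In some lists fewer were named. Exceptions are the genes called by the 6-pair fit or on replicates 2 and 3 alone, further members of the metallothionein list, and the examples in the overlap, which were chosen after their values were seen.

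The procedure was tested on simulated data with known changes in 3 against 3 arrays. For doxycycline in PMA-treated cells it called 23.9% of genes changed by 0.5 (log2), 92.5% of those changed by 1 and 100% of those changed by 2, with 0 false calls among 19575 unchanged genes. The 6-pair fit called 37.3%, 98.5% and 100%, with 7 false calls. For PMA the shares were 23.9%, 97% and 100%, with 10 false calls. A changed list of 15 genes was called, and 0 of 23 random lists were. The simulated genes varied independently of one another, so neither the false calls nor the list result covers genes that move together. The simulated arrays shared a deviation within each of the 6 pairs. The result of the 6-pair fit therefore assumes the pairing and does not test it.

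The alternatives tried were the replicate block, leaving out each array, a filter on genes with a mean under 5, the mean of a gene's probe sets, all probe sets, no probe sets of shared sequence, a variance trend, median centring, cyclic loess, a fit on the compared groups alone, a change of at least 1 (log2), and the estimated correlation.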

Results

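Gene expression was measured on 12 Affymetrix HG-U133 Plus 2.0 arrays, 1 per culture, in U937 cells, a human histiocytic lymphoma line with features of immature monocytes. The cells carried a Tet-On cassette that makes a hairpin RNA against ZXDC, a zinc finger protein gene, when doxycycline is added. Cultures received PMA, a phorbol ester that drives U937 cells toward a macrophage-like state, or its DMSO vehicle, each with and without doxycycline. The 4 groups were vehicle, vehicle with doxycycline, PMA, and PMA with doxycycline, with 3 arrays each, named by the labels as biological replicates 1 to 3. The median signal was between 5.16 and 5.22 (log2) on every array.

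PMA separated the arrays most. Along the first principal component, which held 79.7% of the variance, the 6 vehicle arrays lay between -55.1 and -47.6 and the 6 PMA arrays between 43.1 and 59.3. Arrays of 1 group correlated at 0.987 to 0.996, and arrays of different agents at 0.954 to 0.967. The 4 arrays numbered 1 stood apart in an RNA quality measure, the 3' minus 5' signal of the ACTB control probe sets. It averaged 2.37 (log2) on them, with a lowest value of 1.99, against 1.15 on the other 8 arrays, whose highest value was 1.64. The mean of this ratio was 1.89 ± 0.73 (SD, n = 3) in PMA with doxycycline and 1.51 ± 0.76 (n = 3) in PMA, a difference of 0.39 with an exact permutation p of 0.5 that leaves pairs aside. By pairs it was higher with doxycycline in 3 of 3 PMA pairs (2.72 against 2.39, 1.32 against 1.12 and 1.64 against 1.01) and in 2 of 3 vehicle pairs. In vehicle with doxycycline and in vehicle it was 1.39 ± 0.89 and 1.44 ± 0.49, a difference of -0.05 with an exact permutation p of 1. The 3' minus 5' signal of the GAPDH control probe sets did not set the arrays numbered 1 apart. It was 0.17 to 0.25 on them and 0.12 to 0.25 on the others. In the PMA pairs it was 0.25 with doxycycline against 0.18 without, 0.19 against 0.15 and 0.17 against 0.18.

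The first question was whether doxycycline lowered ZXDC, the gene the hairpin targets. ZXDC signal, read from its probe set of highest mean, went from 7.78 ± 0.20 (log2, SD, n = 3) to 7.28 ± 0.14 in vehicle-treated cells and from 7.78 ± 0.24 to 7.28 ± 0.23 in PMA-treated cells. The log2 differences were -0.49 (SE 0.16) and -0.50 (SE 0.16), so that 71.1% and 70.6% of the signal was left. Averaged over both agents the difference was -0.50 (SE 0.11), and ZXDC was lower in 6 of 6 pairs of arrays. An exact permutation of the arrays within each agent (two-sided, 400 relabelings) gave p = 0.005, the smallest it can give. On the arrays numbered 2 and 3 alone the averaged difference was -0.39, with an exact permutation p of 0.0556, the smallest that so few arrays can give. All 6 ZXDC probe sets were lower with doxycycline in both agents, by averaged differences of -0.63 to -0.25, and 4 of them had an exact permutation p under 0.05. None of the 5 probe sets for ZXDA and ZXDB, the close relatives of ZXDC, had an exact permutation p under 0.05, and their averaged differences lay between -0.07 and 0.15. Over all 19775 genes the fall of ZXDC did not pass limma's adjusted test in either agent, with an adjusted p of 0.613 in PMA and 1 in vehicle.

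**Figure D1:**
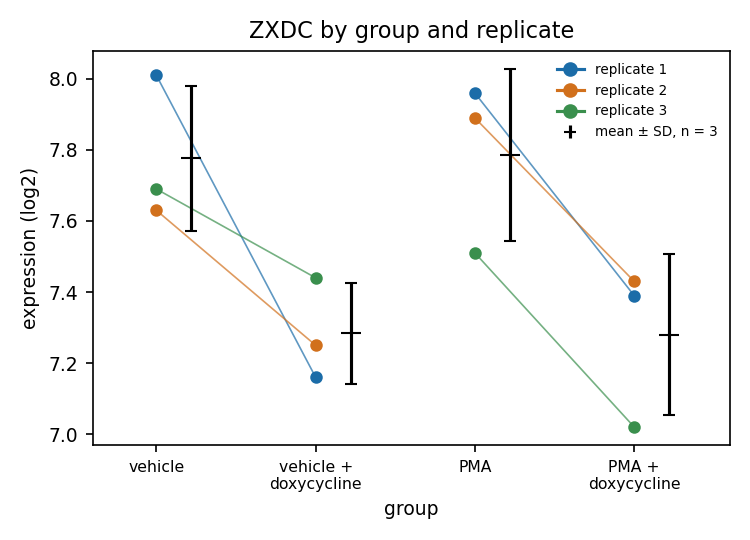
ZXDC expression (log2) on the 12 arrays by group. Points are arrays, lines join arrays of the same replicate number, and bars give the mean ± SD (n = 3). The group means are 7.78 without and 7.28 with doxycycline under both agents.

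The second question was what PMA did with the hairpin off. PMA moved 6260 of 19775 genes, 31.7%, of which 2518 rose and 3742 fell. SPP1, which encodes the secreted matrix protein osteopontin, rose by 10.61 (log2, SE 0.37) from 3.95 ± 0.75 to 14.56 ± 0.14 (SD, n = 3), and the collagenase gene MMP1 rose by 8.80 (SE 0.37). In the other direction, the myeloid membrane gene MS4A3 fell by 4.66 (SE 0.31) and CTSG, the gene for the granule protease cathepsin G, fell by 3.90 (SE 0.28). Cell cycle genes and granule protein genes fell as groups, while chemokine, lysosome and protease genes rose, each by a list test that also held with an estimated correlation.

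Other genes among the 10 with the largest rise were TDO2, a tryptophan-degrading enzyme (8.17), ZFP36L1, an mRNA decay factor (8.08), GPR82 (7.53), EMP1, a membrane protein (7.39), GPR34, a lysophospholipid receptor (7.01), FABP4, a fatty acid carrier of macrophages and fat cells (7.00), IER3, an early response gene (6.98), and VWF, von Willebrand factor (6.93). The genes with the largest falls after MS4A3 and CTSG were INPP4B, a phosphoinositide phosphatase (-3.87), PLAC8 (-3.87), NEGR1 (-3.83), GAPT (-3.71), BLNK, a signalling adaptor (-3.61), RNASE2, an eosinophil and monocyte granule ribonuclease (-3.53), ELANE, neutrophil elastase (-3.51), and LAMP5 (-3.46). Some of these sizes lean on dim signals. The vehicle means of SPP1, MMP1, TDO2 and GPR82 lay at percentiles 28.2, 27.2, 15.4 and 1.52 of all probe sets, and SPP1 under PMA was close to the highest signals on those arrays, 14.82 to 14.88, so neither the exact sizes nor their order is well measured. The same holds for falls to dim signals, with PMA means of 3.33 for INPP4B, 3.96 for NEGR1, 3.71 for GAPT and 3.88 for BLNK. Sizes and order also depend on the probe set. By the mean of a gene's probe sets, ZFP36L1 differed by 3.30, TDO2 by 4.52, FABP4 by 4.03, VWF by 3.61, INPP4B by -1.74 and NEGR1 by -2.07, all still past the test, and among list members named below ITGAX by 2.44, ATF3 by 2.02, ABCA1 by 1.76, CDKN2B by 2.07, NPC1 by 1.62, CFLAR by 0.82, CCND2 by -0.75, MRPL19 by -0.69 and BCL2 by -0.57. The adjusted p of the 20 genes lay at or below 8.72e-06. CCL2, a monocyte-attracting chemokine, rose from 6.78 ± 0.92 to 12.71 ± 0.63 (5.92, SE 0.64, adjusted p = 7.05e-06), and BCL6, a transcriptional repressor, rose by 2.70 (SE 0.29, adjusted p = 6.19e-06). CIITA, the activator of MHC class II genes, differed by 0.16 (SE 0.11) with an adjusted p of 0.357. ZXDC differed by 0.01 (SE 0.16), its other 5 probe sets by -0.45 (SE 0.17) to 0.31 (SE 0.16), and the ZXDA signal fell by 0.94 (SE 0.16, adjusted p = 0.000338). ZXDB differed by -0.47 (SE 0.20, adjusted p = 0.102). Without PMA replicate 1 or PMA with doxycycline replicate 3 it was -0.67 and -0.47, with an adjusted p of 0.0147 and 0.0485. With the replicate block it was -0.47 with an adjusted p of 0.0344, and on the arrays numbered 2 and 3 alone -0.60 with an adjusted p of 0.0276. The reference genes ACTB and GAPDH differed by -0.28 (SE 0.20) and 0.05 (SE 0.10), neither past the test.

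**Figure D2:**
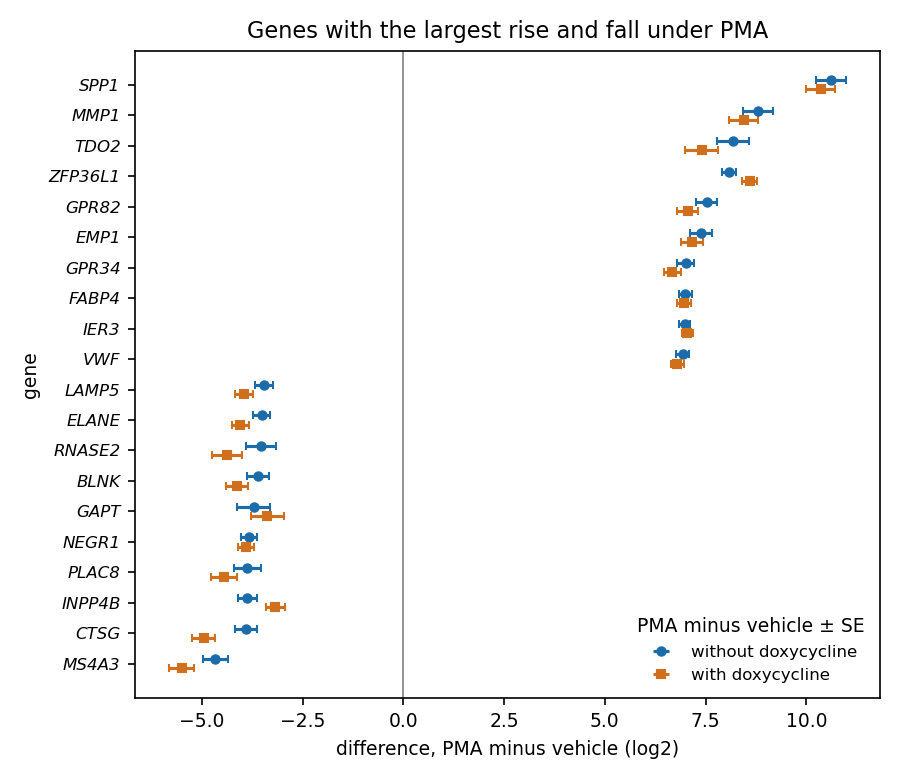
Difference of PMA minus vehicle (log2) for the 10 genes with the largest rise and the 10 with the largest fall, without doxycycline (circles) and with doxycycline (squares); bars give the SE. SPP1 has the largest rise, 10.61 without and 10.35 with doxycycline.

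Of 24 gene lists, 17 shifted as a whole with PMA by limma's camera test, 13 up and 4 down, and 9 of these also passed with an estimated correlation between genes. By fry, a rotation test, 18 lists passed. The lists of BCL6 repressed genes and of chemokines hold CCL2 and were drawn up with knowledge of the study, so they are not independent evidence for that gene. Leaving out 1 array changed the call of 3 lists, each named below.

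Genes of cell division fell together. In the list of cell cycle and DNA replication genes 29 of 30 members fell (29 adjusted over the list alone), with a median of -1.95 and an adjusted p of 1.50e-18 (adjusted p = 0.0484 with an estimated correlation). They included MCM5, part of the replicative helicase (-2.83, SE 0.26), and TYMS, thymidylate synthase (-2.44, SE 0.15). Granule and progenitor genes fell in 9 of 12 members (9 over the list alone), with a median of -1.99 and an adjusted p of 3.50e-07 (adjusted p = 0.0484 with an estimated correlation). Mitochondrial ribosome and translation genes fell in 20 of 22 members and rose in 1 (21 and 1 over the list alone), with a median of -0.72 and an adjusted p of 5.08e-08. MRPL19, a subunit of the mitochondrial ribosome, fell by 1.16 (SE 0.17) and TUFM, a mitochondrial elongation factor, fell by 0.99 (SE 0.15). This call was lost with an estimated correlation (adjusted p = 0.0732 with an estimated correlation). Nuclear-encoded respiratory chain genes fell in 7 of 23 members (7 over the list alone), with a median of -0.23 and an adjusted p of 0.0331 (adjusted p = 0.396 with an estimated correlation). NDUFS3 (-0.69, SE 0.12) and NDUFA9 (-0.64, SE 0.11), both of complex I, fell. Without vehicle replicate 2 or PMA replicate 1 this list had an adjusted p of 0.0564 and 0.0976. On arrays numbered 2 and 3 alone it had 0.115, without dim genes 0.114, and after cyclic loess a median of -0.13 and 0.307.

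Lists of macrophage and inflammatory genes shifted upward at the preset correlation, 3 of 6 of them also with an estimated one. Of the monocyte and macrophage markers 15 of 22 rose and 0 fell (15 up and 1 down adjusted over the list alone), with a median of 1.94 and an adjusted p of 7.07e-09. CHIT1, a chitinase of activated macrophages, rose by 5.64 (SE 0.50) and ITGAX, the integrin CD11c, by 4.81 (SE 0.17). The call was lost with an estimated correlation (adjusted p = 0.0692 with an estimated correlation). Chemokines and cytokines rose in 18 of 28 members (19 over the list alone), with a median of 1.22 and an adjusted p of 7.07e-09 (adjusted p = 0.0367 with an estimated correlation). CXCL8, the neutrophil attractant interleukin 8, rose by 6.11 (SE 0.49). NF-kB responsive genes rose in 11 and fell in 2 of 16 members (12 and 2 over the list alone), with a median of 0.81 and an adjusted p of 3.88e-06 (adjusted p = 0.0211 with an estimated correlation). CD83, a surface marker of activated antigen-presenting cells, rose by 3.46 (SE 0.21) and BCL2A1, a survival protein, by 3.14 (SE 0.13), while PTX3, a secreted pattern recognition protein, fell by 2.05 (SE 0.24). AP-1 and EGR factors rose in 10 and fell in 1 of 14 members (10 and 1 over the list alone), with a median of 1.57 and an adjusted p of 2.06e-07 (adjusted p = 0.0346 with an estimated correlation). EGR3 rose by 5.36 (SE 0.30) and ATF3 by 3.90 (SE 0.14), and BATF fell by 0.55 (SE 0.10). Type I interferon response genes rose in 9 and fell in 1 of 21 members (11 and 1 over the list alone), with a median of 1.17 and an adjusted p of 0.00287 (adjusted p = 0.522 with an estimated correlation). Without PMA replicate 3 the median was 0.48 (adjusted p = 0.0333), and on the arrays numbered 2 and 3 alone 1.83. OAS1, an antiviral RNA sensor, rose by 4.48 (SE 0.52) and IFI6 by 3.29 (SE 0.43). Complement and coagulation genes rose in 7 and fell in 1 of 16 members (8 and 1 over the list alone), with a median of 0.62 and an adjusted p of 2.45e-05 (adjusted p = 0.0692 with an estimated correlation). C3, the central complement protein, rose by 5.11 (SE 0.23) and F13A1, a clotting factor subunit, fell by 2.18 (SE 0.31).

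Genes of the matrix, the lysosome and metabolism also shifted upward. Proteases, adhesion and matrix genes rose in 16 of 23 members (16 up and 1 down over the list alone), with a median of 1.30 and an adjusted p of 1.24e-09 (adjusted p = 0.0472 with an estimated correlation). Lysosome genes rose in 13 of 18 members (14 over the list alone), with a median of 0.90 and an adjusted p of 2.65e-08 (adjusted p = 0.0487 with an estimated correlation). ATP6V0D2, a subunit of the proton pump, rose by 4.77 (SE 0.13) and NPC1, a lysosomal cholesterol transporter, by 2.60 (SE 0.13). LXR and PPARG lipid genes rose in 10 and fell in 2 of 17 members (10 and 3 over the list alone), with a median of 0.49 and an adjusted p of 0.00225 (adjusted p = 0.0472 with an estimated correlation). ABCA1, a cholesterol exporter, rose by 3.67 (SE 0.24), and CPT1A, which starts the import of fatty acids into mitochondria, fell by 1.55 (SE 0.10). Cholesterol synthesis genes rose in 8 and fell in 1 of 13 members (11 and 1 over the list alone), with a median of 0.57 and an adjusted p of 0.000108 (adjusted p = 0.316 with an estimated correlation). Without vehicle replicate 1 the median was 0.37. MSMO1 and SQLE, both sterol-making enzymes, rose by 1.71 (SE 0.18) and 1.65 (SE 0.19). Glycolysis and hypoxia response genes rose in 9 and fell in 3 of 18 members (9 and 3 over the list alone), with a median of 0.28 and an adjusted p of 0.00429 (adjusted p = 0.0472 with an estimated correlation). Over all probe sets this call was lost (median 0.08, adjusted p = 0.0618). SLC2A3, a glucose transporter, rose by 3.35 (SE 0.19) and BNIP3, a mitophagy receptor, fell by 0.77 (SE 0.14). Metallothioneins and heme or oxidative stress genes rose in 12 of 15 members (13 over the list alone), with a median of 0.68 and an adjusted p of 3.11e-07 (adjusted p = 0.0724 with an estimated correlation). SRXN1, which repairs oxidised peroxiredoxins, rose by 2.09 (SE 0.16) and HMOX1, heme oxygenase, by 1.87 (SE 0.29).

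BCL6 repressed genes rose in 6 and fell in 2 of 13 members (6 and 2 over the list alone), with a median of 0.45 and an adjusted p of 0.0389 (adjusted p = 0.121 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 4.59 (SE 0.25) and CCND2, cyclin D2, fell by 1.28 (SE 0.17). Without vehicle replicate 1 or PMA replicate 2 the list had an adjusted p of 0.0509 and 0.0544. Without dim genes it had 0.0803. The other 7 lists did not pass the test, although 4 did over all probe sets: MHC class I presentation (median 0.58, adjusted p = 0.000138), stress response (0.18, 0.0296), apoptosis (0.23, 0.0194) and other lineages (0.03, 0.0377). MHC class II genes had a median of 0.09 (adjusted p = 0.356), with CTSS and HLA-DMA up by 1.32 and 1.28 and RFX5, a class II regulator, down by a difference of -1.06. MHC class I presentation genes had a median of 0.45 (adjusted p = 0.128), and on arrays numbered 2 and 3 alone 0.63 with an adjusted p of 0.0494. The cyclin-dependent kinase inhibitors had a median of -0.01, a mean of 1.13 and a test direction of up (adjusted p = 0.325). In it CDKN1A and CDKN2B (3.67, SE 0.29) rose and CDKN1B fell by 1.17 (SE 0.16). Myeloid transcription factors had a median of 0.22, a mean of -0.15 and a test direction of up (adjusted p = 0.873). CEBPB rose by 1.80 (SE 0.11), and MYB (-2.85, SE 0.26) and GFI1 (-2.22, SE 0.19), both factors of immature blood cells, fell. The integrated stress response genes had a median of 0.16 (adjusted p = 0.119), and 0.28 without PMA replicate 2 or PMA replicate 3, with an adjusted p of 0.0476 and 0.0415. GDF15, a stress-induced cytokine, rose by 5.65 (SE 0.61), but by 0.34 with an adjusted p of 0.201 once probe sets of shared sequence were left out. Apoptosis regulators had a median of 0.15 (adjusted p = 0.585), with MCL1 and CFLAR up by 1.26 and 1.39 and BCL2 and FAS down, to differences of -1.52 and -1.10. Genes of other lineages had a median of -0.00, a mean of 0.46, a test direction of up and an adjusted p of 0.251, and the endothelial genes VWF and PECAM1 were the only 2 of 22 to pass, both upward.

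**Figure D3:**
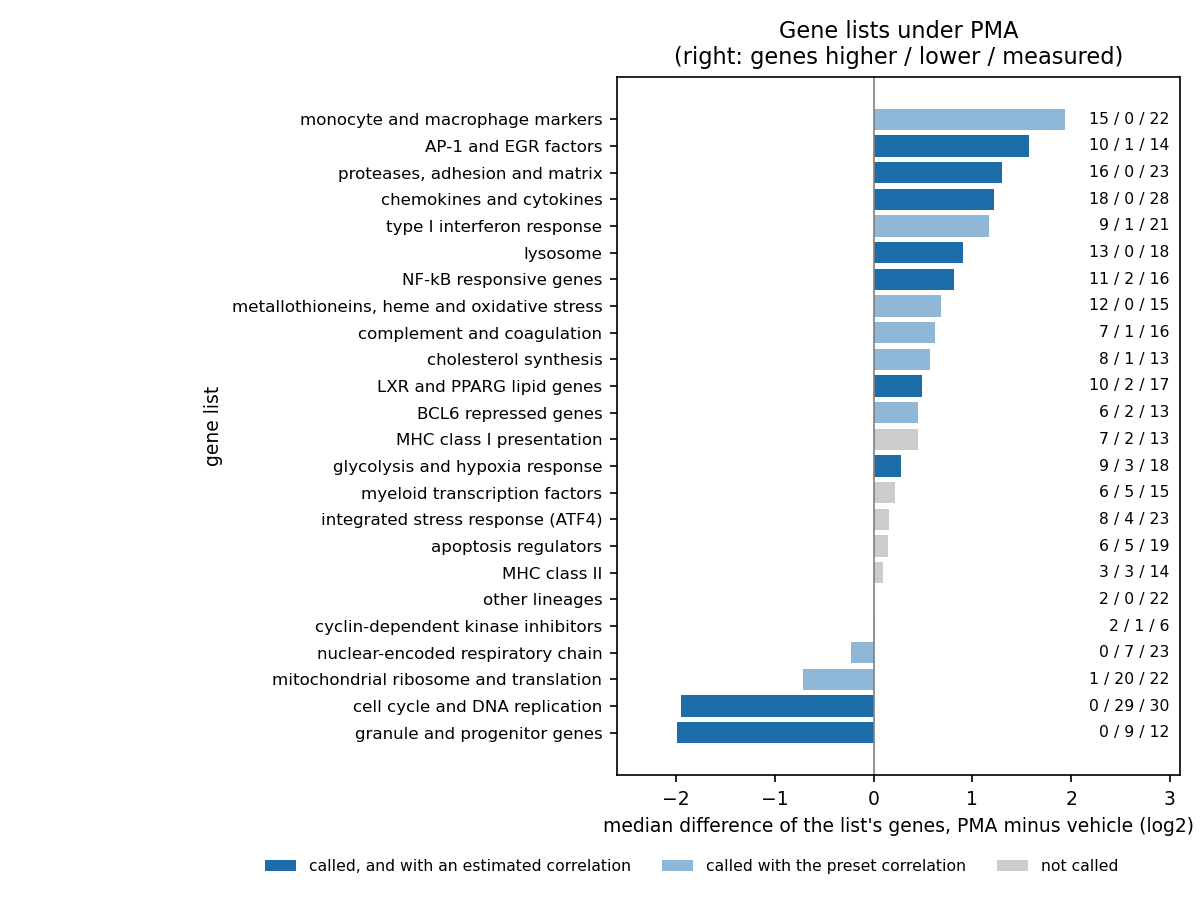
Median difference of PMA minus vehicle (log2) for the 24 gene lists, coloured by the result of the test. Numbers at the right give the genes higher, lower and measured; cell cycle genes have 29 of 30 lower and a median of -1.95.

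A change of at least 1 (log2) was seen in 2138 of the 6260 genes, 898 up and 1240 down. At an unadjusted p under 0.05 there were 7633 genes, and in 8268 genes, 41.8%, the PMA and vehicle arrays did not overlap, against a chance share of 10%.

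The same question was asked with the hairpin induced. With doxycycline PMA moved 6426 genes, 2571 up and 3855 down, and SPP1 (10.35, SE 0.37), ZFP36L1 (8.59, SE 0.18) and MMP1 (8.44, SE 0.37) led the rises. MS4A3 (-5.50, SE 0.31), CTSG (-4.95, SE 0.28) and PLAC8 (-4.45, SE 0.33) led the falls. By the mean of its probe sets ZFP36L1 differed by 3.41. CCL2 rose by 4.93. Of the genes called, 5427 were called both with and without doxycycline, and 5426 of these moved in the same direction. Across genes, which are not independent replicates, the effects had a Pearson r of 0.965 and a slope of 0.988. A change of at least 1 (log2) was seen in 2289 genes, and in 8410 genes, 42.5%, the arrays did not overlap, against a chance share of 10%. Camera called 17 lists here, 13 up and 4 down, of which 5 held with an estimated correlation. No gene had an interaction, a difference between the PMA effects with and without doxycycline, past limma's adjusted test (0 genes, with 518 at an unadjusted p under 0.05). With the arrays paired the count was 1, HES1, with 1284 at an unadjusted p under 0.05.

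The main question of the series was which genes doxycycline moved in PMA-treated cells. HES1, a transcriptional repressor known as a Notch target, rose by 1.48 (log2, SE 0.18, adjusted p = 0.0214), and was the only gene of 19775 to pass limma's test without pairing. HES1 was higher in 3 of 3 pairs, by 1.34, 1.67 and 1.43. With the replicate block over all groups, chosen before the data were seen, 2 genes passed, HES1 and HTRA1. With arrays of the same replicate number paired within agents, a fit chosen after seeing the data, 53 genes passed, 27 up and 26 down. Each of the 53 moved alike in 3 of 3 pairs, which this fit favours by construction. Whether PMA arrays numbered 2 and 3 are matched pairs was itself not settled by the data. Among them HTRA1, PRDM1 and CD300A rose, as did the probe sets assigned to the metallothioneins MT1E, MT1X, MT1H and MT1HL1, whose sequence is shared within the family, so that which of these genes rose is not settled. CCL2, TREM2, VSIG4 and C3AR1 fell, while the list of monocyte and macrophage markers did not shift (median 0.04, mean -0.05, adjusted p = 0.94). The ACTB 3' minus 5' signal was also higher with doxycycline in these 3 pairs.

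The genes with the largest paired rises after HES1 were HTRA1, a secreted serine protease (1.46, paired SE 0.13, adjusted p = 0.00271), GPRC5B, an orphan receptor (1.42, SE 0.17, adjusted p = 0.0211), C11orf96 (1.20), RRN3P2 (1.08), EFNB2, the ligand ephrin-B2 (1.03), PRDM1, the repressor Blimp-1 (0.91), HES4, a relative of HES1 (0.90), KIAA1671 (0.90) and SNAI1, a zinc finger repressor (0.89). HES4 was read by a probe set of shared sequence. The shared-sequence probe sets of MT1E and MT1X differed by 0.88 (paired SE 0.13, adjusted p = 0.031) and 0.76 (paired SE 0.10, adjusted p = 0.0211). The largest paired falls were those of CCL2 (-1.10, paired SE 0.18, adjusted p = 0.0477), RAB7B, a small GTPase of endosomes (-1.02), PRKACB, a catalytic subunit of protein kinase A (-0.90), VSIG4, a complement receptor of macrophages (-0.84), CUTALP (-0.84), RASGRP3, a Ras activator responsive to phorbol esters (-0.81), KCTD12 (-0.81), PLAC8 (-0.79), RNASE2 (-0.79) and TREM2 (-0.76). CCL2 went from 12.71 ± 0.63 to 11.61 ± 1.19 (SD, n = 3) and was lower in 3 of 3 pairs (-1.74, -0.74 and -0.82). Without pairing its adjusted p was 0.855. In vehicle-treated cells its difference was -0.11 (SE 0.64), and the difference between agents, -0.99 (SE 0.91), did not pass (adjusted p = 1; 0.631 with pairing). BCL6 differed by 0.01 (SE 0.29) and CIITA by -0.11 (SE 0.11), neither past the test with or without pairing. The CIITA signal was near the dim limit, with means of 5.36 in PMA and 5.26 in PMA with doxycycline. ZXDA and ZXDB differed by 0.02 (SE 0.16) and 0.17 (SE 0.20), and ACTB and GAPDH by -0.19 (SE 0.20) and -0.07 (SE 0.10).

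**Figure D4:**
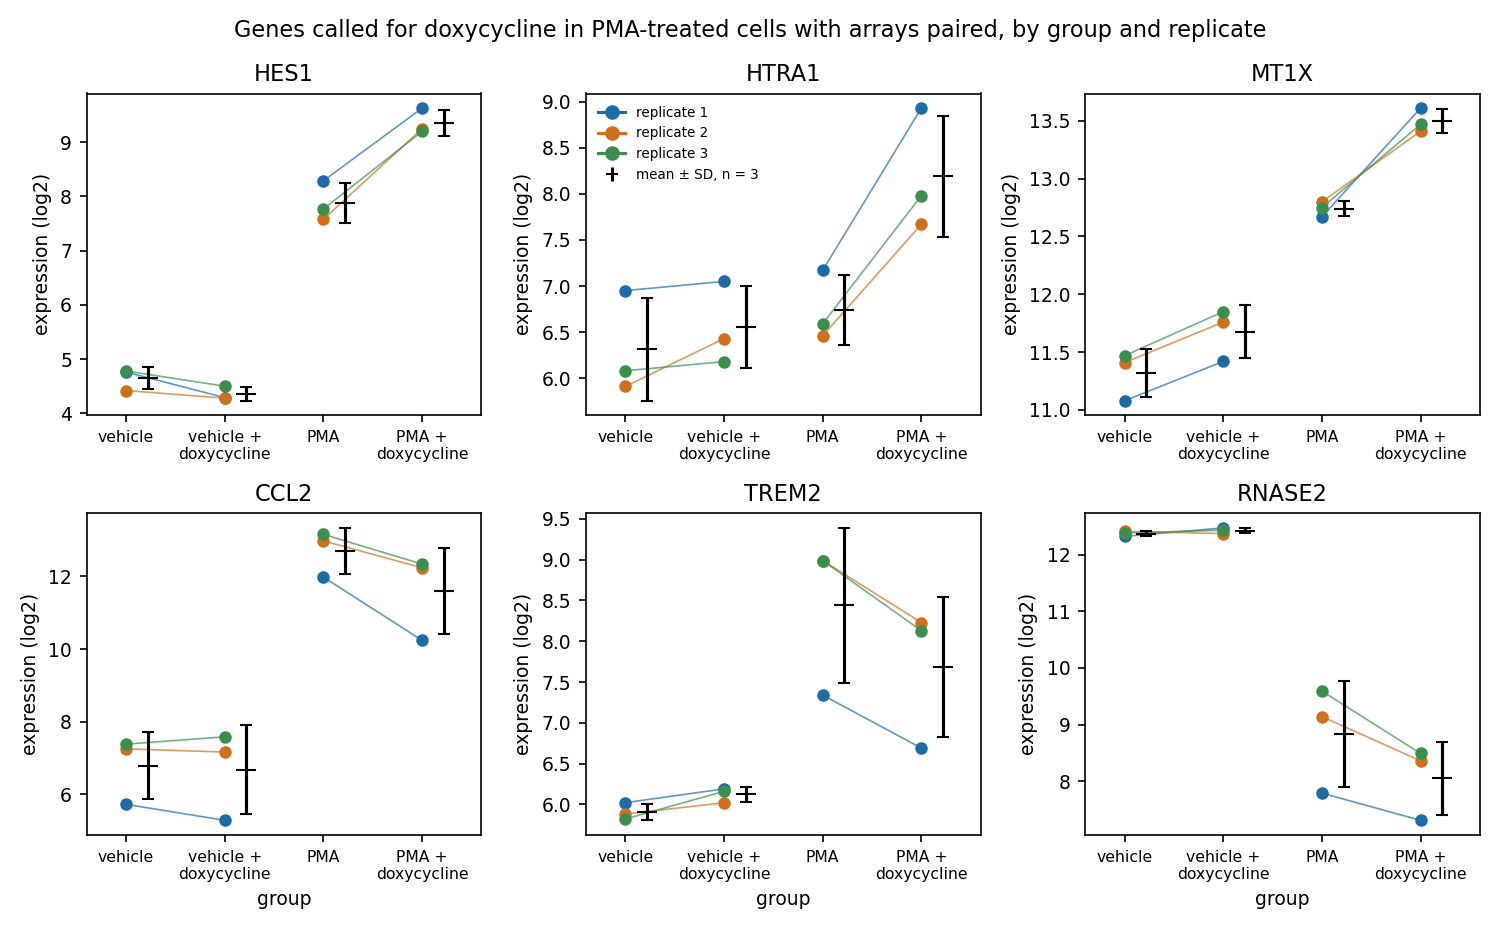
Expression (log2) of 6 genes on the 12 arrays by group; points are arrays, lines join arrays of the same replicate number, and bars give the mean ± SD (n = 3). In PMA-treated cells HES1, HTRA1 and MT1X are higher and CCL2, TREM2 and RNASE2 lower with doxycycline in 3 of 3 pairs. All 6 were picked from the genes called with arrays paired.

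Gene lists moved less in this comparison, and no call of a list held with an estimated correlation. By fry 0 lists passed in one direction (1 with pairs) and 1 in mixed directions (13 with pairs), against 5 by camera. Metallothioneins and heme or oxidative stress genes shifted up (median 0.23, adjusted p = 2.62e-07), with 0 of 15 members past the test over all genes and 6 adjusted over the list alone. With an estimated correlation this was lost (adjusted p = 0.518 with an estimated correlation). The members adjusted over the list alone that passed were metallothioneins, small metal-binding proteins read by probe sets of shared sequence. MT1X differed by 0.76 (SE 0.14), MT1E by 0.88 (SE 0.17) and MT2A by 0.58 (SE 0.13), each higher in 3 of 3 pairs, while HMOX1 differed by -0.19 (SE 0.29) and NQO1 by -0.32 (SE 0.26). With probe sets of shared sequence left out, the list had a median of -0.03 and an adjusted p of 0.754 by camera. This cannot test the metallothioneins, because 10 of 12 MT1 and MT2 probe sets are of shared sequence. The others were dim, with means of 4.67 and 3.24. Granule and progenitor genes shifted down (median -0.28, adjusted p = 0.00153), with 0 of 12 members past the test over all genes and 2 adjusted over the list alone (adjusted p = 0.518 with an estimated correlation). CTSG differed by -0.95 (SE 0.28) and was lower in 3 of 3 pairs. Cholesterol synthesis genes shifted up (median 0.19, adjusted p = 0.00491), with 0 of 13 members past either test and 12 of 13 above 0, among them STARD4, a sterol carrier (0.32, SE 0.16). With an estimated correlation its adjusted p was 0.801, and without PMA replicate 1 or PMA with doxycycline replicate 2 it was 0.145 and 0.159. Apoptosis regulators shifted down (median -0.19, adjusted p = 0.0111), with 0 of 19 members past either test, among them the death receptor gene FAS (-0.42, SE 0.17). With an estimated correlation this gave an adjusted p of 0.518, and without PMA replicate 2, PMA replicate 3 or PMA with doxycycline replicate 1 an adjusted p of 0.0863, 0.0588 and 0.13. Cell cycle and DNA replication genes shifted down (median -0.14, adjusted p = 0.0357), with 0 of 30 members past either test. TYMS differed by -0.42 (SE 0.15). With an estimated correlation the list had an adjusted p of 0.921. Without PMA replicate 1, PMA replicate 3, PMA with doxycycline replicate 2 or PMA with doxycycline replicate 3 it had an adjusted p of 0.254, 0.0547, 0.156 and 0.597, the last with a median of 0.02. The number of lists called, 5, was 3 without PMA replicate 3, 3 without PMA with doxycycline replicate 2, and 8 without PMA with doxycycline replicate 1. The other 19 lists had an adjusted p of at least 0.205, among them the BCL6 repressed genes (median -0.11, adjusted p = 0.94), in which PRDM1 differed by 0.91 (SE 0.22), and the chemokines and cytokines (median -0.00, mean -0.13, adjusted p = 0.94).

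The calls rested on few arrays. The HES1 call without pairing was lost without vehicle replicate 3 (adjusted p = 0.0539), vehicle with doxycycline replicate 2 (0.0624) or 3 (0.0507), PMA replicate 2 (0.097) or 3 (0.261), and PMA with doxycycline replicate 1 (0.117), 2 (0.055) or 3 (0.0734), with HES1 differences of 1.33 to 1.56. It was also lost by the mean of its probe sets, where the difference was 0.97 (adjusted p = 0.114), over all probe sets (0.066) and in a fit of the 2 groups alone (0.69). The paired count of 53 fell to 8, 13 and 4 genes without the PMA pair 1, 2 or 3, and to 24, 16 and 20 without the vehicle pair 1, 2 or 3. HES1 and HTRA1 passed each time, and CCL2 passed in none of these, with an adjusted p of 0.18, 0.054, 0.192, 0.0506, 0.0944 and 0.0627. On the arrays numbered 2 and 3 alone, without pairing, 9 genes passed. HES1, HTRA1 and EFNB2 were higher and CCL4, CTSG, GINS2, MS4A3, PLAC8 and TREM2 lower, and 5 of the 9 were among the 53. At an unadjusted p under 0.05 there were 1214 genes without pairing, against 989 expected by chance, and 2601 with pairing. In 2122 genes, 10.7%, the arrays did not overlap, against a chance share of 10%.

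In vehicle-treated cells the same comparison asked what doxycycline did without PMA. No gene passed limma's test (0 genes without pairing and 0 with, with 510 and 1090 at an unadjusted p under 0.05). The genes with the smallest p, none past the test, were VIM, the filament protein vimentin (0.68, SE 0.13), PPP4R4 (-0.77, SE 0.16), ADGRG3 (0.51, SE 0.11), NDFIP2 (-0.52, SE 0.12) and DMRTB1 (0.49, SE 0.12), all with an adjusted p of 1 and moving alike in 3 of 3 pairs. BCL6 differed by 0.21 (SE 0.29) and CIITA by 0.14 (SE 0.11). Camera called 2 lists, both upward and both lost with an estimated correlation (adjusted p = 0.929 with an estimated correlation for each), and fry called 0. Metallothioneins and heme or oxidative stress genes had a median of 0.17 (adjusted p = 0.00239), with MT2A at 0.41 (SE 0.13). Without probe sets of shared sequence the median was 0.04 (adjusted p = 0.562), and the call was also lost by probe set mean (0.0667) and over all probe sets (0.0612). The first of these settings removes most metallothionein probe sets, so it cannot test the metallothioneins. Without vehicle replicate 1, vehicle with doxycycline replicate 2 or vehicle with doxycycline replicate 3 the list had an adjusted p of 0.185, 0.199 and 0.0908. Proteases, adhesion and matrix genes had a median of 0.16 (adjusted p = 0.0348), and without vehicle replicate 3, vehicle with doxycycline replicate 2 or vehicle with doxycycline replicate 3 an adjusted p of 0.195, 0.199 and 0.119. In neither list did a member pass the test over all genes, or without pairing adjusted over the list alone; with pairs 4 members of the metallothionein list passed the latter. The count of 2 lists was 4 without vehicle replicate 1, 1 without vehicle with doxycycline replicate 2, and 0 without vehicle with doxycycline replicate 3. In 1692 genes, 8.56%, the arrays did not overlap, against a chance share of 10%.

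Averaged over both agents, no gene passed without pairing (0 by limma, with 1198 at an unadjusted p under 0.05), and HTRA1 passed with pairing (0.85, paired SE 0.09, adjusted p = 0.0358, higher in 6 of 6 pairs, with 2442 genes at an unadjusted p under 0.05). The smallest unpaired p belonged to MT1HL1 (0.46, SE 0.08), EMB, a membrane glycoprotein (-0.51, SE 0.09), MT1X (0.56, SE 0.10), MT1H (0.46, SE 0.08) and MT1G (0.43, SE 0.08), each moving alike in 6 of 6 pairs and with an adjusted p of 0.323 to 0.368. The 4 metallothionein values come from probe sets of shared sequence. Camera called 5 lists. Metallothioneins (adjusted p = 4.90e-08) and cholesterol synthesis genes (adjusted p = 0.00235) were up. Apoptosis regulators (adjusted p = 0.00235), granule genes (adjusted p = 0.0169) and cell cycle genes (adjusted p = 0.02) were down. None held with an estimated correlation (lowest adjusted p = 0.451 with an estimated correlation). The count was 9 without PMA with doxycycline replicate 1 and 2 without PMA with doxycycline replicate 2.

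The difference between the doxycycline effects of PMA-treated and vehicle-treated cells had its smallest p for HES1, at 1.78 (SE 0.25, with vehicle means of 4.65 and 4.36 near background), which passed with pairing (adjusted p = 0.00328) and missed without it (adjusted p = 0.133). HES1 was higher with doxycycline in 3 of 3 PMA pairs and lower in 3 of 3 vehicle pairs. Without PMA replicate 1 the difference was 1.98 and passed without pairing (adjusted p = 0.00672). With the replicate block it passed as well (adjusted p = 0.0269), and by the mean of its probe sets it was 0.90 (adjusted p = 1). MYCL, a MYC family gene (0.97, SE 0.17), GRHL1 (1.34, SE 0.26), C11orf96 (1.33, SE 0.27) and HES4 (0.97, SE 0.20) followed, with an adjusted p of 0.603 to 0.821. Camera called granule genes (median -0.39) and metallothioneins with stress genes (median 0.18), both with an adjusted p of 0.0159 (adjusted p = 0.973 with an estimated correlation). The count of 2 lists was 4 without vehicle replicate 1 or PMA replicate 1, 5 without PMA with doxycycline replicate 1, and 1 without vehicle with doxycycline replicate 1, PMA replicate 2 or PMA replicate 3. It was 0 without vehicle replicate 2, vehicle replicate 3 or PMA with doxycycline replicate 2.

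Whether doxycycline moved the same genes with and without PMA was tested on all genes. The differences in vehicle-treated and PMA-treated cells, which share no arrays, had a Pearson r of 0.22 and a Spearman rho of 0.21 across genes, which are not independent replicates. An exact permutation of the arrays within agents gave p = 0.1 and 0.11, with 0.01 the smallest it can give. That null ignores the pairs. Over the 64 exchanges within pairs, a test added after seeing the data, the exact permutation p was 0.188, with 0.0625 the smallest it can give, so it could not pass 0.05. Without vehicle replicate 1, vehicle with doxycycline replicate 2 or PMA replicate 2 r was 0.26, 0.24 and 0.28, with an exact permutation p of 0.04, 0.03 and 0.03. Without vehicle with doxycycline replicate 1 or PMA replicate 1 it was 0.08 and 0.12, and on the arrays numbered 2 and 3 alone 0.06. No gene was called in both agents by limma (0), while 63 had an unadjusted p under 0.05 in both, 49 of them in the same direction, against 31.3 if the lists were independent. The 2 tests of a gene share 1 estimate of its spread, which can raise the number passing both without a shared effect. The value of 31.3 is therefore only a rough reference.

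Genes that doxycycline moved in PMA-treated cells were compared with those that PMA moved. Without pairing HES1 was called in both; the count of 1 was 0 without any of the 8 arrays whose absence ended the HES1 call. Of the 53 genes called with pairing 39 were also moved by PMA. Both comparisons use the PMA arrays, so no count expected by chance is set beside this. In 12 both changes were upward, as in HES1, PRDM1 and CD300A, an inhibitory receptor of myeloid cells. In 17 both were downward, as in RNASE2, PLAC8 and EMB. In 7 PMA raised the gene and doxycycline lowered it, as in CCL2, TREM2, TDO2 and C3AR1, and in 3 PMA lowered it and doxycycline raised it, as in C11orf96. The shared arrays alone give a negative relation across genes. In simulated groups with no doxycycline effect the correlation across genes was -0.10 on average (-0.13 to -0.08), and the observed value was 0.13; the covariance was -0.012 in the simulations and 0.016 observed. The simulated arrays vary independently, without the replicate structure of the real ones, so their range is too narrow to serve as a test of this value.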

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

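The tests of the metallothionein rise by probe set sequence and by doxycycline itself were chosen after that result was seen, and the fit with pairs of arrays was chosen after seeing the data. Groups of 3 arrays were not tested for outliers.

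The HES1 effect of doxycycline differed between PMA-treated and vehicle-treated cells by 1.78 (log2), past the test with pairs of arrays, but its vehicle means of 4.65 and 4.36 lie under the dim limit of 5, so the size is uncertain. For the granule and progenitor genes the median difference was -0.39, and for the metallothioneins with heme or oxidative stress genes 0.18, both past the camera test and lost with an estimated correlation. Among probe sets with no single gene name, which the comparisons do not use, 2095 of 13522 were called with PMA, 1131 higher and 964 lower.

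The 53 genes called with doxycycline in PMA-treated cells were weighed against RNA quality and against other splits of the arrays. The ACTB 3'/5' ratio was taken as a slope times its difference between groups. It gave a median share of 0.13 of the change of these genes (quartiles -0.00 to 0.22), under the 0.5 set beforehand. The slope came from arrays within groups, where the ratio mainly parted the arrays numbered 1 from the others. The ratio was also higher with doxycycline in 3 of 3 PMA pairs, so this share cannot decide whether RNA quality added to the changes. Of 4 splits that part all pairs, 1 called as many genes as the real 53, the real one itself, and the highest other called 0, but 4 splits cannot give a share under 0.05. Without pairing 3 of 10 splits called at least 1 gene (highest other 1). For gene lists 5 of 10 splits called at least the real 5, with 12 the highest other. The splits that put both arrays numbered 1 together called 10 to 12 against 0 to 3 for the others, which sets the arrays numbered 1 apart. Splits that kept both arrays numbered 2 together, and both numbered 3, called 0 and 1. They therefore show no such structure for numbers 2 and 3.

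Single metallothioneins passed the paired test over all genes with doxycycline in PMA-treated cells, and none did in vehicle-treated cells. The mean of 7 metallothionein genes, picked after their rise was seen, differed by 0.49 averaged over agents (0.68 in PMA, 0.29 in vehicle). Of 12 MT1 and MT2 probe sets 10 are of shared sequence, and 0 with sequence of their own had a mean of at least 5, so that which metallothionein rose, and whether several did, stays open. The design had 0 groups given doxycycline whose cells hold no hairpin, so doxycycline itself may account for the rise as well as the loss of ZXDC, and this holds for every doxycycline effect here.

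The 10 regroupings of 3 against 3 arrays cannot give a share under 0.05. PMA without doxycycline called 6260 genes and 17 lists, reached by 1 and 1 of 10 splits (highest other 0 and 16). With doxycycline it called 6426 genes and 17 lists, reached by 1 and 2 of 10 (highest other 0 and 17). Doxycycline in vehicle-treated cells called 0 genes and 2 lists, reached by 10 and 6 of 10 (highest other 0 and 6). For the averaged effect 100 of 100 splits drawn reached the 0 genes and 44 the 5 lists (highest other 1 and 14), and for the interaction 100 reached the 0 genes and 73 the 2 lists (highest other 8 and 13). These splits mix agents or replicate numbers, so their list counts are not read as a range for unchanged arrays.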

How the results depend on the processing

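The paired fits and the fit on replicates 2 and 3 alone were chosen after seeing the data. Of 4005 alternatives to 180 gene values 3911 kept direction and side of the threshold, 39 were weaker, 37 stronger and 18 reversed. Of 689 alternatives to 31 list shifts 646 were kept, 36 were weaker, 7 stronger and 0 reversed. The reference was the fit without pairing, so a gene or list uncalled there that stayed uncalled counts as kept. These shares therefore do not measure how stable the doxycycline calls were. The cause of a change was not tested, except that a stricter threshold calls less by construction. Fewer arrays did not always call less. On replicates 2 and 3 alone PMA-changed genes numbered 7019 without and 6998 with doxycycline, against 6260 and 6426 on all arrays. The number of PMA-changed genes lay between 5268 and 6534 without doxycycline and between 5500 and 6671 with it when any 1 array was left out, and it was 12879 and 13401 over all probe sets and 2138 and 2289 at a change of at least 1 (log2). PMA lists numbered 16 to 18 and 16 to 17 without any 1 array. With an estimated correlation 9 and 5 PMA lists held, and 0 of the lists of each doxycycline comparison. The number of genes called for doxycycline in PMA-treated cells, 1, was 2 with the replicate block, 53 with 6 pairs in a paired block, 9 on replicates 2 and 3 alone, 0 by probe set mean, all probe sets or the fit on 2 groups, and 0 to 1 without any 1 array; the 53 were 4 to 24 without any 1 pair. Its overlap with PMA-changed genes, 1, was 2 with the block, 39 with paired arrays, 8 on replicates 2 and 3 alone, 0 in the same 3 settings, and 0 to 1 without any 1 array. Its lists, 5, were 3 by probe set mean or cyclic loess, 8 on replicates 2 and 3 alone, and 3 to 8 without any 1 array. In vehicle-treated cells the 0 genes stayed 0, and the 2 lists were 0 by probe set mean or all probe sets, 1 without probe sets of shared sequence and 0 to 4 without any 1 array. The averaged effect had 1 gene with the block, 1 with paired arrays and 3 on replicates 2 and 3 alone; its 5 lists were 8 by probe set mean, 9 over all probe sets, 8 on replicates 2 and 3 alone and 2 to 9 without any 1 array. The interaction had 1 gene with the block, 1 with paired arrays and 0 to 1 without any 1 array; its 2 lists were 1 with the block, 1 with paired arrays, 1 without probe sets of shared sequence and 0 to 5 without any 1 array. ZXDC fell by 0.43 to 0.57 (averaged differences of -0.57 to -0.43) without any 1 array and differed by -0.39 on replicates 2 and 3 alone, where fewer relabelings make the smallest possible p larger. The correlation of doxycycline effects, 0.22, lay between 0.08 and 0.28 without any 1 array. Values near 0 changed sign: ZXDC with PMA by median centring (-0.03; -0.08 to 0.14 without any 1 array), BCL6 with doxycycline in PMA-treated cells by probe set mean (-0.01; -0.28 to 0.35), CCL2 in vehicle-treated cells on replicates 2 and 3 alone (0.06; -0.64 to 0.59), and CXCL2 without probe sets of shared sequence (0.02). Without any 1 array ZXDA lay between -0.11 and 0.14, ACTB between -0.37 and 0.05, CCL2 between -1.47 and -0.42, TREM2 between -1.31 and -0.26 and VSIG4 between -1.80 and 0.17 for doxycycline in PMA-treated cells. With the replicate block PMA-changed genes numbered 7000 without and 7165 with doxycycline. The averaged effect then had 6 lists, as it did with paired arrays. The replicate block changed no number of called genes or lists other than those given here. Low signal limits dim genes, since a change is compressed near background.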

Other observations

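The tests of the PMA axis and of the stress response were chosen after the doxycycline results were seen.

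Arrays with doxycycline lay further along the PMA axis, the difference of the vehicle and PMA means scaled to 100%. The mean shift was 4.21%, with 5.42% in PMA and 2.99% in vehicle, and all 6 of 6 pairs shifted toward PMA. Over all relabelings within agents the exact permutation p was 0.105, and over the 64 exchanges within pairs it was 0.0312, the smallest possible. The shift predicted from the ACTB 3'/5' ratio was -2.5% in PMA and -0.132% in vehicle, against the direction seen. The slopes behind it had opposite signs, -6.46 (SE 1.59) in PMA and 2.74 (SE 0.99) in vehicle. Within groups the ratio mainly parted the arrays numbered 1 from the others, so this prediction cannot decide on RNA quality as a source of the shift.

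HES1 and HES4 rose together, although HES4 was read by a probe set of shared sequence, with a PMA mean of 5.56. The hypothesis of a wider rise of Notch target genes with doxycycline in PMA-treated cells was therefore tested on 8 other targets. The camera p was 0.538, and the 8 targets, 5 of them with a mean of at least 5, differed by 0.05 on average. The 95% interval was -0.09 to 0.18, under the bound of 0.3 set beforehand. It was taken over genes, which are not independent replicates, and some of the targets were dim. The 8 targets thus showed no shared rise, but a wider rise of Notch targets is not excluded. Doxycycline can inhibit mitochondrial translation, and the hypothesis of an ATF4 stress response was tested on the 23 integrated stress response genes. They differed by 0.04 (SE 0.04) averaged over agents, with an exact permutation p of 0.575, which leaves the question open.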
